A study of Arabidopsis thaliana with 12 samples.

How the data were processed

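Rosettes of wild-type and med25-1 plants were profiled by RNA sequencing of poly(A) RNA with a stranded kit, per the labels' protocols. Seeds were stratified for 48 h at 4 °C and grown on plates with 0.5% sucrose at 21 °C by day and 18 °C by night, with 16 h of light at 150 µmol per square metre and second and 8 h of dark, per the labels' protocols. After 3 weeks plants were held at 1% oxygen for 3 h or kept as controls, with 3 biological replicates in each of 4 groups. Groups and replicate numbers were taken from the titles and treatment labels. The read mapping and counting tools are not given in the sources used here, and the genome build is TAIR10 per the submitters' processing notes.

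The deposited table held 33208 features in 293 columns, of which 106 were used or described and 186 were not used. Per the file headers, each library had counts of reads in each gene, given as uniquely placed and total gene reads, uniquely placed and total exon reads and uniquely placed intron reads. The counts used as the main measure were uniquely placed gene reads, which equalled exon plus intron reads for every feature and library. The authors also deposited RPKM values, made from total exon reads and exon length per the file headers, and these were not tested. The authors deposited a further signal per gene, quantile-normalized gene reads, whose sorted values were identical in all 12 libraries. A score and p-values per comparison came from the authors' own Baggerley's test on proportions, with a signed fold change and an FDR corrected p-value per the file headers. Start positions in the file count from 0 and are printed here counting from 1, and 32909 features matched the TAIR10 reference annotation by identifier, 32908 of them with the same start and end. The table held 152 mitochondrial genes, and chloroplast genes were not analysed here.

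Totals of gene reads ran from 7170796 to 20501572 per library, and intron reads were 1.59% to 2.53% of them. A single gene with no read over 3 libraries was given a floor of 3 counts over the group, and a fold against it is printed as a lower bound. Groups with 1 to 3 counts were given a ratio with an exact 95% counting interval. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 4.17 to 81.9, so that no library was a copy of another. The counting strand is not given in the sources used here, so values of antisense and overlapping genes are uncertain. Near-identical genes, such as the PDF1.2, RBCS, small heat shock and KIN families, lose reads that fit more than 1 locus, and their values are uncertain as well.

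Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 18212, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, which share 1 estimate of the spread (common dispersion 0.0436), and 5 contrasts were tested two-sided with Benjamini-Hochberg adjustment within each, at an adjusted p under 0.05. The standard error printed is the log2 fold change divided by the root of the F statistic and is approximate. CPM used TMM library sizes, and list scores and log2 values used a prior count of 2. On simulated counts for 18212 genes with 100 changed per size, 45% of 2-fold and 88% of 4-fold changes were recovered for hypoxia in wild type with 13 false calls. For the genotypes under control conditions these were 45%, 91% and 8, and for the interaction 14%, 69% and 5.

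The design, the alternatives, 22 gene lists and the rule for named genes were fixed before the data were examined. Named genes were, per contrast, the 8 largest positive and 8 largest negative log2 fold changes among called genes with a mean of at least 50 counts per library in the higher group and, for pairwise contrasts, no overlap between the libraries of the groups. Added to these were MED25, ADH1, PDC1, SUS4, HB1, LBD41, PCO1, PCO2, HRE1, HRE2, HRA1, RAP2.12, RAP2.2 and RAP2.3, and up to 3 called members of each list with the smallest p, or the single one with the smallest p where none was called. The lists were core hypoxia genes, sucrose breakdown, glycolysis and fermentation, oxygen sensing (group VII factors and their N-degron pathway), Mediator subunits, general jasmonate genes, the jasmonate and ethylene defence branch, salicylate, flowering, circadian, heat shock, ethylene, mitochondrial and oxidative stress, photosynthesis, ribosome biogenesis, cell cycle, flavonoid and anthocyanin, sugar starvation, iron, abscisic acid with cold and osmotic stress, light and shade, and root and floral markers as other tissues the samples could hold. The 19 lists with at least 5 tested genes were tested with limma 3.58.1's camera on 95 list and contrast pairs adjusted together, with a preset correlation of 0.01, then with an estimated correlation and with fry. Of the 39 preset calls, 5 held with an estimated correlation: core hypoxia genes in both genotypes, oxygen sensing in wild type, and abscisic acid, cold and osmotic genes in wild type and for the interaction. The core hypoxia list shares genes with glycolysis, oxygen sensing, ethylene, oxidative stress and jasmonate lists.

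The alternatives were RLE scaling, DESeq2 1.42.0, no filter, a stricter filter (CPM of at least 1 in 3 libraries), a fit of only the groups compared, the replicate number as a block, each replicate left out, mitochondrial genes left out, a change of at least 2-fold and a prior count of 0.5. Unique exon reads, edgeR's robust dispersion, limma's voom with sample weights, limma on the quantile-normalized signal, the replicate number as a block among the hypoxia libraries only, with labels swapped within those pairs for the core score, and set tests with that block or with each replicate left out, and CPM means, fold bounds and list counts with each replicate left out, were chosen after seeing the data. Whether replicate numbers pair the libraries was checked by the correlation of deviations from group means, since the labels name no shared batch or day. Between wild-type and med25-1 hypoxia libraries the 3 same-numbered pairs gave 0.114 to 0.49, each over 0.1, and the 6 other pairs -0.33 to 0.189. The ranges overlapped, since wild-type replicate 2 correlated more with med25-1 replicate 3 (0.189) than with med25-1 replicate 2 (0.114). The numbers were fitted as possible pairs of these libraries, which neither the labels nor these values establish. No other pair of groups had every same-numbered correlation over 0.1. Tables were read with the R package data.table, version 1.17.8, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Exact permutation tests were two-sided and enumerated every arrangement.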

Results

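RNA was measured by sequencing in rosettes of Arabidopsis thaliana, from wild-type plants and from med25-1, a mutant line of MED25. MED25 is a subunit of Mediator, the complex that links transcription factors to RNA polymerase II. Plants were 3 weeks old and were kept under control conditions or held at 1% oxygen for 3 h, a treatment called hypoxia here. Each of the 4 groups had 3 biological replicates, 12 libraries in all. The total of gene reads was 14224663, 11360247 and 19149540 in the wild-type control libraries and 17031412, 14467262 and 20501572 in the med25-1 control libraries, in the order of replicates 1 to 3. It was 13853874, 12512275 and 14568888 in the wild-type hypoxia libraries and 14009905, 18310640 and 7170796 in the med25-1 hypoxia libraries. The shallowest library, med25-1 hypoxia replicate 3, also stood apart in content: its 20 most abundant genes took 8.97% of its reads, against 14.8% and 14.0% in the other libraries of its group. A gene is called changed below where its Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test lay under 0.05 among 18212 tested genes. Levels are counts scaled to library size (CPM) with their SD, and log2 fold changes carry a standard error (SE).

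The targeted gene was examined first in every library. MED25 (AT1G25540, chromosome 1, 8969065 to 8974815) on TAIR10 stood at 34.6, 32.7 and 34.9 CPM in the wild-type control libraries and at 22.8, 20.7 and 31.2 CPM in the med25-1 control libraries. Under hypoxia it stood at 26.2, 38.0 and 33.8 CPM in wild type and at 14.2, 15.3 and 21.5 CPM in med25-1. MED25 transcript was therefore present in all 6 libraries of the mutant line, and the position of the lesion is not given in the sources used here. The difference between genotypes was -0.45 ± 0.20 (SE) on the log2 scale under control conditions (edgeR adjusted p = 0.133) and -0.96 ± 0.20 under hypoxia (edgeR adjusted p = 0.0066). Hypoxia itself gave a log2 change of MED25 of -0.06 ± 0.19 in wild type (edgeR adjusted p = 0.925) and of -0.56 ± 0.20 in med25-1 (edgeR adjusted p = 0.116). The second of these passed the threshold without med25-1 hypoxia replicate 3, at -0.75 with an edgeR adjusted p of 0.0476, in a range of 0.0476 to 0.39 over its alternatives. Reads outside its exons set the lines apart: they made up 1.06% ± 0.732 (SD, n = 3) of MED25 reads in wild-type control and 8.78% ± 1.41 in med25-1 control. Under hypoxia they made up 1.24% ± 0.146 in wild type and 9.24% ± 2.52 in med25-1. The share ran from 0.457% to 1.88% over the wild-type libraries and from 7.36% to 12.1% over the med25-1 libraries. The highest exact Clopper-Pearson 95% bound of a wild-type library was 3.83%. The lowest such bound of a med25-1 library was 3.86%, and these bounds cover counting error only. The mean of the 6 med25-1 libraries exceeded that of the 6 wild-type libraries by 7.86 percentage points (two-sided exact permutation test, 924 arrangements, p = 0.00216). An exact test of 3 libraries against 3 cannot go below p = 0.1. This share was chosen as a check of the labels after its values were seen.

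**Figure D1:**
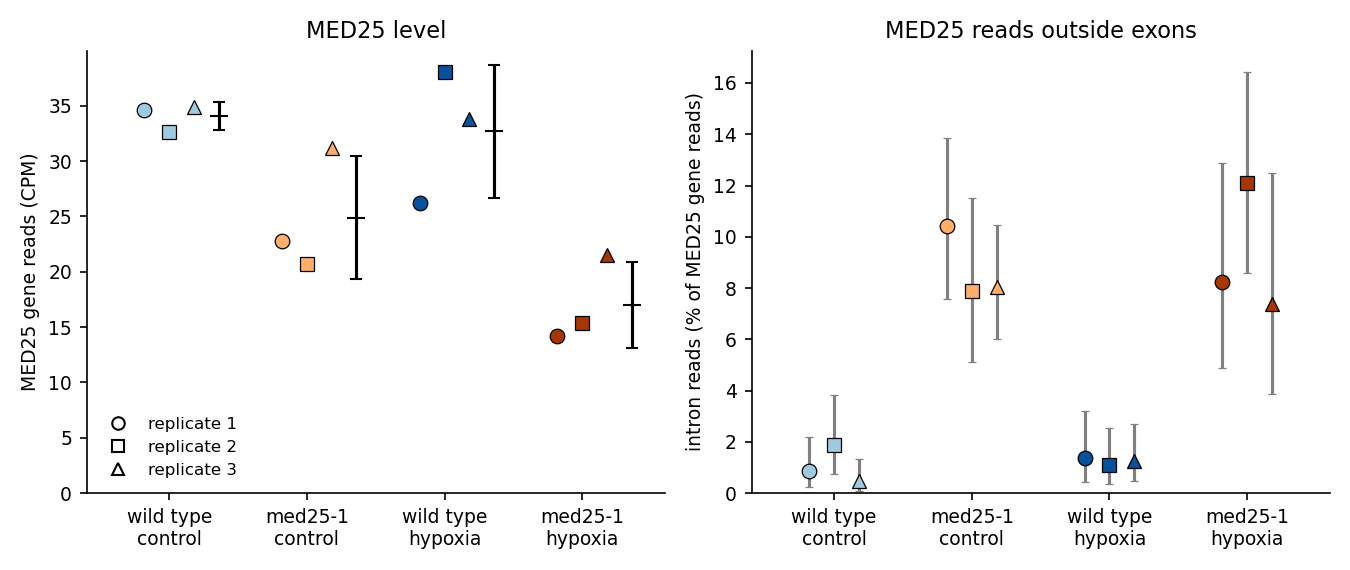
MED25 gene reads in CPM (left, y axis from 0, black bars mean ± SD of 3 libraries) and the percent of MED25 reads outside exons (right, grey bars exact 95% Clopper-Pearson intervals) in each of the 12 libraries, by group. The intron share lies between 0.457% and 1.88% in wild-type libraries and between 7.36% and 12.1% in med25-1 libraries.

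The first comparison asked which genes responded to 3 h of hypoxia in wild type. Of the 54 tested genes on the core hypoxia list, genes known to respond to low oxygen across cell types, 44 rose. PCO1 (AT5G15120, chromosome 5, 4898641 to 4900734), a plant cysteine oxidase that marks the group VII ethylene response factors for degradation, rose from 0.419 ± 0.0405 CPM (SD, n = 3) to 135 ± 7.11 CPM, a log2 fold change of 8.32 ± 0.25 (SE; edgeR adjusted p = 4.8e-09). HB1 (AT2G16060), a phytoglobin that scavenges nitric oxide, rose by 6.65 ± 0.27 to 384 ± 29.1 CPM. ADH1 (AT1G77120, chromosome 1, 28975255 to 28977417), alcohol dehydrogenase, rose from 2.87 ± 1.06 CPM to 175 ± 62.2 CPM (log2 fold change 5.90 ± 0.36, edgeR adjusted p = 1.7e-06). Among the genes that fell were XTH15 (AT4G14130), a xyloglucan-modifying enzyme, which fell by 6.21 ± 0.72 on the log2 scale, and AGP7 (AT5G65390), an arabinogalactan protein, which fell by 3.70 ± 0.39. XTH15 had a log2 fold change of -5.45, -6.86 and -5.62 without wild-type control replicate 1 and wild-type hypoxia replicates 1 and 3 in that order.

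In wild type 1181 genes were called, 556 higher (47.1%) and 625 lower under hypoxia. The core hypoxia list counted 44 risen and 1 fallen, with 47 up and 1 down when adjusted over the list alone. The list moved together in limma's camera test with a preset correlation (adjusted p = 1.1e-190, and adjusted p = 4.9e-05 with an estimated correlation). The one that fell was PHI-1 (AT1G35140), at -2.16 ± 0.46, named after its values were seen and a call lost without wild-type control replicate 1 or wild-type hypoxia replicate 1 or 3 (adjusted p up to 0.0735). LBD41 (AT3G02550), a transcription factor, rose by 5.72 ± 0.25 and AT3G27220, a kelch-repeat protein, by 4.57 ± 0.19. The rhodanese-family gene AT2G17850 had no read over the control libraries and was at least 351-fold higher under hypoxia. PDC1 (AT4G33070), pyruvate decarboxylase, had 3 reads over the control libraries and 1564 under hypoxia, a ratio of 569 with a 95% counting interval of 194 to 2761. The ethylene response factor HRE2 (AT2G47520) went from 1 read to 261, a ratio of 285 with a 95% counting interval of 50.7 to 11291. Of 33 genes of glycolysis and fermentation, 7 of them shared with the core list, 12 rose and 1 fell, with 15 up and 1 down when adjusted over the list alone (camera adjusted p = 5.3e-14, adjusted p = 0.112 with an estimated correlation). The fallen one was FBA5 (AT4G26530), an aldolase, at -1.55 ± 0.37, named after its values were seen and a call lost without wild-type control replicate 1, 2 or 3 or wild-type hypoxia replicate 1 or 3 (adjusted p up to 0.107). SUS1 (AT5G20830), sucrose synthase, rose by 4.36 ± 0.39 and PFK6 (AT4G32840), a phosphofructokinase, by 2.78 ± 0.18. SUS4 (AT3G43190) rose by 2.67 ± 0.57, a call lost without wild-type control replicate 1, 2 or 3 or wild-type hypoxia replicate 2 or 3 (adjusted p up to 0.0761 over the alternatives). Of 16 genes of oxygen sensing 4 rose and 1 fell, with 4 up and 1 down when adjusted over the list alone (camera adjusted p = 8.0e-16, adjusted p = 0.0235 with an estimated correlation). Those that rose were PCO1, HRE2, PCO2 (AT5G39890) at 7.19 ± 0.32 and HRA1 (AT3G10040), a factor that restrains RAP2.12, at 7.03 ± 0.38. The constitutive factors RAP2.12 (AT1G53910) and RAP2.2 (AT3G14230) were not called, at 0.12 ± 0.13, edgeR adjusted p = 0.714 and -0.10 ± 0.23, edgeR adjusted p = 0.894. HRE1 (AT1G72360) was not called either, at 0.15 ± 0.37, edgeR adjusted p = 0.896. RAP2.3 (AT3G16770) fell by 1.15 ± 0.25 on the log2 scale, a call lost without wild-type control replicate 1 or wild-type hypoxia replicate 1 or 3 (adjusted p up to 0.0813 over the alternatives). AT2G17850 and HRE2 differed by at least 199.8-fold and 54.1-fold without wild-type control replicate 3. PDC1 had a ratio of 972 without wild-type control replicate 3. PHI-1 had a log2 fold change of -1.41 without wild-type control replicate 1.

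Beyond the anaerobic genes, 12 of 19 genes of the abscisic acid, cold and osmotic response list rose in wild type and 0 fell, with 14 up and 0 down when adjusted over the list alone (camera adjusted p = 1.6e-16, adjusted p = 0.0203 with an estimated correlation). The cold-response activator CBF3 (AT4G25480) rose by 2.57 ± 0.26 and COR15B (AT2G42530), a cold-regulated chloroplast protein, by 2.80 ± 0.37. Of 27 jasmonate genes 3 rose, with 11 up and 0 down when adjusted over the list alone (camera adjusted p = 1.4e-05, adjusted p = 0.573 with an estimated correlation). JAZ2 (AT1G74950), a jasmonate repressor, rose by 1.44 ± 0.26. Of the 3 tested genes of the jasmonate and ethylene defence branch 2 rose, PDF1.2A (AT5G44420), a defensin, by 3.57 ± 0.49 and PR4 (AT3G04720) by 1.08 ± 0.25, the latter a call lost without wild-type control replicate 2 or 3 or wild-type hypoxia replicate 2 or 3 (adjusted p up to 0.106 over the alternatives). PDF1.2A had a log2 fold change of 4.28 without wild-type control replicate 3. Among 16 ethylene genes 2 rose and 4 fell: the receptor ETR2 (AT3G23150) rose by 2.57 ± 0.19 and the receptor ERS1 (AT2G40940) fell by 1.19 ± 0.12. The median of that list was -0.21 and its mean 0.02 (camera adjusted p = 0.274). Of 15 mitochondrial and oxidative stress genes 2 rose (camera adjusted p = 0.0060, adjusted p = 0.631 with an estimated correlation). Mitochondrial and oxidative stress genes had a mean log2 fold change of 0.43, which was 0.72 without wild-type control replicate 3. The universal-stress protein HRU1 (AT3G03270) rose by 3.11 ± 0.27 and the NADPH oxidase RBOHD (AT5G47910) by 2.46 ± 0.28. Heat shock genes counted 2 risen of 15 (camera adjusted p = 0.023, adjusted p = 0.748 with an estimated correlation). The salicylate list of 18 and the ribosome biogenesis list of 15 had no called member, though 1 and 4 salicylate genes were called without med25-1 control replicate 2 and med25-1 hypoxia replicate 3. Salicylate was called higher as a list (camera adjusted p = 0.00197, adjusted p = 0.748 with an estimated correlation) and ribosome biogenesis lower (camera adjusted p = 0.00754, adjusted p = 0.753 with an estimated correlation). The other lists were not called. Of these, circadian genes counted 1 up and 1 down of 16, with RVE8 (AT3G09600) at 1.07 ± 0.15, and light and shade genes 3 up and 1 down of 16. Iron genes counted 1 up and 1 down of 11, with the ferritin FER4 (AT2G40300) at -1.67 ± 0.19, and photosynthesis genes 1 down of 24. Median, mean and camera direction differed in sign for Mediator (-0.00, 0.03, higher, adjusted p = 0.979) and iron (0.16, 0.19, lower, adjusted p = 0.927). They also differed for light and shade (0.14, -0.12, higher, adjusted p = 0.563). Adjusted over the list alone, the counts were 3 up and 1 down for circadian genes, 3 up and 1 down for mitochondrial and oxidative stress genes and 0 up and 0 down for photosynthesis genes. They were 4 up and 3 down for light and shade genes. The lists with no such count given kept theirs. No member was called of Mediator (33 tested), flowering (11), cell cycle (11), flavonoid (5) or sugar starvation (15). The floral gene PI (AT5G20240), the only floral marker tested, rose by 2.67 ± 0.34, and neither of 2 tested root markers was called.

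The wild-type count moved with the libraries in the fit. It was 641, 629 and 618 without wild-type control replicates 1, 2 and 3. It was 759, 710 and 559 without wild-type hypoxia replicates 1, 2 and 3, and 1933 without med25-1 hypoxia replicate 3. It was 2408 in a fit of the wild-type libraries alone, 5469 with limma's voom and sample weights, and 650 when a change of at least 2-fold was also required. Higher calls outnumbered lower ones with DESeq2 (50.2% higher), in the fit of the wild-type libraries alone (51.5%) and without med25-1 control replicate 3 (51.0%). They did so too without wild-type hypoxia replicates 1, 2 and 3 (50.5%, 50.3% and 50.1%).

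The second comparison asked for the same response in med25-1. PCO1 rose there from 0.0911 ± 0.087 CPM (SD, n = 3) to 102 ± 8.78 CPM, a log2 fold change of 9.93 ± 0.29 (SE; edgeR adjusted p = 3.3e-09). HB1 rose by 7.30 ± 0.27 to 572 ± 111 CPM, ADH1 by 5.35 ± 0.35 to 140.5 ± 33.1 CPM, and PDC1 rose to 14.3 ± 7.23 CPM (edgeR adjusted p = 3.4e-04). Among the genes that fell were AGP17 (AT2G23130), an arabinogalactan protein, which fell by 3.50 ± 0.35, XTH6 (AT5G65730), a xyloglucan-modifying enzyme, which fell by 3.32 ± 0.43, and the gibberellin-responsive GASA1 (AT1G75750), which fell by 3.19 ± 0.47. PCO1 had a log2 fold change of 10.59 without med25-1 control replicate 1, where its control mean was 0.050 CPM.

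In med25-1 961 genes were called, 342 higher (35.6%) and 619 lower. By comparison DESeq2 called 992 higher and 934 lower, a share of 51.5% higher, and the share was 51.0% without med25-1 control replicate 2. Of the 54 core hypoxia genes 40 rose and 1 fell, with 44 up and 1 down when adjusted over the list alone (camera adjusted p = 3.0e-141, adjusted p = 9.3e-05 with an estimated correlation). The fallen one was PHI-1 again, at -2.06 ± 0.48, a call lost without med25-1 control replicate 1 or 3 or med25-1 hypoxia replicate 1 or 3 (adjusted p up to 0.118). LBD41 rose by 5.64 ± 0.25 and HRA1 by 6.75 ± 0.38. SAD6 (AT1G43800), of the stearoyl carrier-protein desaturase family, had 1 read over the control libraries and 1735 under hypoxia, a ratio of 2204 with a 95% counting interval of 395 to 87103, and AT2G17850 was at least 263-fold higher. SAD6 and AT2G17850 differed by at least 452-fold and 162-fold without med25-1 control replicate 3. Glycolysis and fermentation counted 9 risen and 1 fallen of 33, with 15 up and 1 down when adjusted over the list alone (camera adjusted p = 2.5e-11, adjusted p = 0.147 with an estimated correlation), and FBA5 was the fallen one at -2.02 ± 0.38. Oxygen sensing counted 4 risen and 1 fallen of 16 (camera adjusted p = 1.1e-10, adjusted p = 0.0512 with an estimated correlation), with a mean of 1.61 and a median of -0.04. PCO2 rose by 6.43 ± 0.33 and RAP2.3 stood at -1.63 ± 0.25. Of 15 sugar starvation genes 5 fell, with 1 up and 10 down when adjusted over the list alone (camera adjusted p = 1.2e-05, adjusted p = 0.418 with an estimated correlation). DIN4 (AT3G13450), a subunit of branched-chain keto acid dehydrogenase, fell by 0.85 ± 0.15, a call lost with only the 2 groups compared fitted (adjusted p up to 0.119 over the alternatives).

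Heat shock genes counted 5 risen and 1 fallen of 15 in med25-1, with 10 up and 1 down when adjusted over the list alone (camera adjusted p = 1.4e-05, adjusted p = 0.474 with an estimated correlation). Mitochondrial and oxidative stress genes counted 3 risen of 15 (camera adjusted p = 8.4e-04, adjusted p = 0.547 with an estimated correlation), HRU1 at 3.19 ± 0.28. Of the abscisic acid, cold and osmotic list 1 of 19 rose, with 6 up and 0 down when adjusted over the list alone (camera adjusted p = 0.00872, adjusted p = 0.493 with an estimated correlation). That gene was CBF3 at 1.05 ± 0.24, a call lost without med25-1 control replicate 1 or 3 or med25-1 hypoxia replicate 2 and with only the 2 groups compared fitted (adjusted p up to 0.184 over the alternatives). The salicylate list had no called member of 18, with 13 up and 0 down when adjusted over the list alone, and was called higher as a list (camera adjusted p = 5.2e-07, adjusted p = 0.547 with an estimated correlation). Its called members were 11, 1, 6 and 4 without med25-1 control replicates 2 and 3 and med25-1 hypoxia replicates 1 and 2 in that order. Beside this, med25-1 hypoxia replicate 3 had a salicylate score, the mean log2 CPM of the list, of 8.30 against 6.39 and 6.58 in replicates 1 and 2. Ethylene genes counted 2 risen and 3 fallen of 16, ETR2 at 2.61 ± 0.20 and ERS1 at -1.04 ± 0.12, with a median of -0.07 and a mean of 0.16 (camera adjusted p = 0.386). Lists without a call held 1 risen jasmonate gene of 27, 1 fallen circadian gene of 16, and 3 risen and 1 fallen light and shade genes of 16. They also held 1 fallen photosynthesis gene of 24, 1 risen ribosome biogenesis gene of 15, and the ferritin FER4 at -1.74 ± 0.19 as the fallen one of 11 iron genes. No member was called of Mediator, flowering, cell cycle, flavonoid, the jasmonate and ethylene defence branch or the root markers. Median, mean and camera direction differed in sign for Mediator (-0.01, 0.01, lower, adjusted p = 0.927) and flowering (0.07, 0.03, lower, adjusted p = 0.927). They also differed for circadian (0.00, 0.00, lower, adjusted p = 0.727) and iron (0.09, 0.02, lower, adjusted p = 0.657). They also differed for light and shade (0.23, -0.08, higher, adjusted p = 0.927). Adjusted over the list alone, the counts were 4 up and 2 down for oxygen sensing genes, 0 up and 0 down for jasmonate genes and 0 up and 1 down for jasmonate and ethylene defence genes. They were 5 up and 5 down for circadian genes, 3 up and 6 down for ethylene genes and 5 up and 0 down for mitochondrial and oxidative stress genes. They were 1 up and 0 down for flavonoid genes and 5 up and 3 down for light and shade genes. The lists with no such count given kept theirs. PI rose by 2.52 ± 0.40, a call lost with only the 2 groups compared fitted (adjusted p up to 0.0605 over the alternatives). The count of calls was 323 and 418 without med25-1 control replicates 1 and 3, and 633 and 634 without wild-type control replicates 2 and 3. It was 604 without wild-type hypoxia replicate 3 and 1841 without med25-1 hypoxia replicate 2. It was 861 without med25-1 hypoxia replicate 3, 175 in a fit of the med25-1 libraries alone and 513 when a change of at least 2-fold was also required. Salicylate genes had a mean log2 fold change of 1.59, which was 0.72 without med25-1 hypoxia replicate 3. Heat shock genes had a mean log2 fold change of 1.56, which was 2.45 without med25-1 control replicate 2. The mitochondrial and oxidative stress call was lost without med25-1 hypoxia replicate 3, where its mean log2 fold change was 0.20 and not 0.72 (adjusted p = 0.151, in a range of 6.5e-05 to 0.547 over its alternatives). The abscisic acid, cold and osmotic call was lost without med25-1 control replicate 1 or med25-1 hypoxia replicate 2 (adjusted p of 0.0618 and 0.105 in that order, in a range of 7.3e-05 to 0.493 over its alternatives). Abscisic acid, cold and osmotic genes had a mean log2 fold change of 0.42, which was 0.27, 0.68 and 0.28 without med25-1 control replicates 1 and 3 and med25-1 hypoxia replicate 2 in that order. Jasmonate genes, not called as a list, were called higher without med25-1 control replicate 3 (adjusted p = 5.2e-04), in a range of 5.2e-04 to 0.938 over its alternatives. Photosynthesis genes, not called as a list, were called lower without med25-1 hypoxia replicate 1 or 2 (adjusted p of 0.00504 and 0.00825 in that order), in a range of 0.00504 to 0.938 over its alternatives. Ribosome biogenesis genes, not called as a list, were called higher without med25-1 control replicate 1 (adjusted p = 0.0416), in a range of 0.0416 to 0.938 over its alternatives. Beside this, the heat shock score of med25-1 control replicate 2 was 2.79, against at most 1.37 in replicates 1 and 3.

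Between the genotypes 192 genes were called higher in both, against 10.4 for independent lists of these sizes, and 357 lower in both, against 21.2. Of the 1593 genes called in either genotype 1528 had the same sign in both. Across all tested genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.659 and Spearman's rho of 0.544, and the comparisons share no library.

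**Figure D2:**
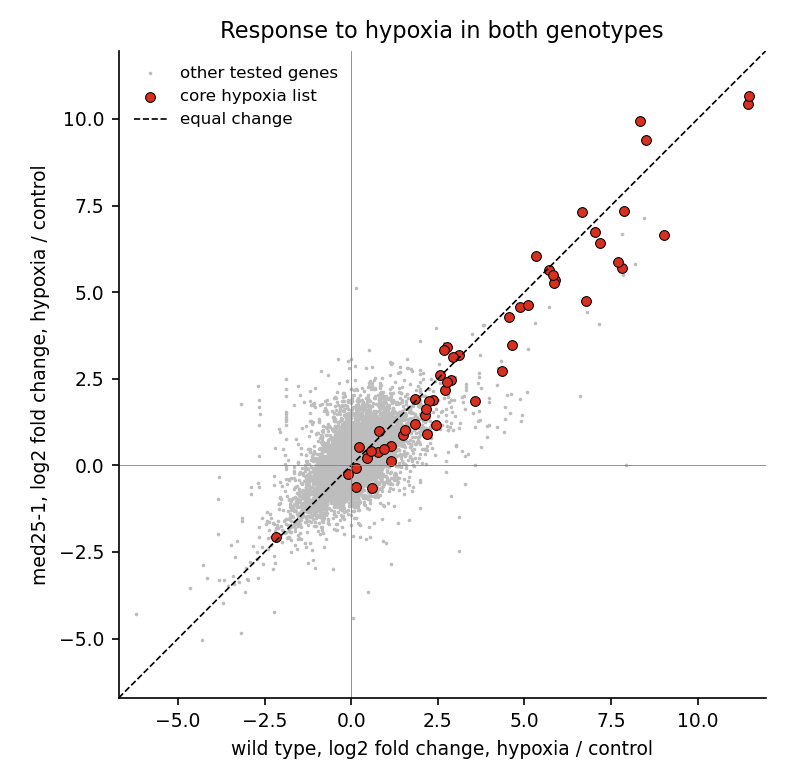
Log2 fold change under hypoxia against control in wild type (x axis) and in med25-1 (y axis) for each tested gene, with the core hypoxia list in red, other genes in grey and the line of equal change dashed. Of the 54 core genes 44 rose in wild type and 40 in med25-1, and Pearson's r over all 18212 genes was 0.659.

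The third comparison asked how med25-1 differed from wild type under control conditions. The salicylate defence genes were far higher in the mutant: all 18 tested genes of that list were called higher, with a median log2 fold change of 4.46. The calls were 17 and the median 3.82 without med25-1 control replicate 2. PR2 (AT3G57260, chromosome 3, 21188397 to 21189967), a pathogenesis-related glucanase, stood at 1.26 ± 0.142 CPM (SD, n = 3) in wild type and 601 ± 525 CPM in med25-1, a log2 fold change of 8.90 ± 0.92 (SE; edgeR adjusted p = 1.1e-04). Its med25-1 mean was 297 CPM without replicate 3. The salicylate regulators SARD1 (AT1G73805) and WRKY70 (AT3G56400) were higher by 5.51 ± 0.61 and 4.51 ± 0.51. PR1 (AT2G14610) had no read over the wild-type control libraries and was at least 1317-fold higher in med25-1, and FMO1 (AT1G19250) and ALD1 (AT2G13810), enzymes of systemic acquired resistance, were at least 248-fold and at least 251-fold higher. PR2 had a log2 fold change of 7.90 without med25-1 control replicate 3. SARD1 and WRKY70 had a log2 fold change of 4.83 and 3.88 without med25-1 control replicate 2. PR1 differed by at least 749.8-fold without wild-type control replicate 3. FMO1 differed by at least 141-fold, 113-fold and 378-fold without wild-type control replicate 3 and med25-1 control replicates 2 and 3 in that order. ALD1 differed by at least 143-fold and 157-fold without wild-type control replicate 3 and med25-1 control replicate 2 in that order. CHS (AT5G13930), chalcone synthase of the flavonoid pathway, was lower in med25-1 than in wild type, where it stood at 10.3 ± 0.592 CPM (edgeR adjusted p = 1.3e-04).

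Under control conditions 3115 genes were called between genotypes, 1635 higher (52.5%) and 1480 lower in med25-1. The salicylate list was called with a preset correlation (camera adjusted p = 9.4e-22) but not with an estimated one (camera adjusted p = 0.156). Limma's fry, which asks whether the genes moved one way on balance, gave an adjusted p of 0.0049. Its 18 members were also called when adjusted over the list alone, and with its 3 genes without wild-type reads at their bound the median was 4.46. The list score was 0.99 ± 0.04 (SD, n = 3) in wild type and 5.47 ± 0.91 in med25-1, whose libraries lay at 5.30, 6.45 and 4.65. Of 15 mitochondrial and oxidative stress genes 7 were higher and 1 lower, with 10 up and 1 down when adjusted over the list alone (camera adjusted p = 0.00239, adjusted p = 0.585 with an estimated correlation). OM66 (AT3G50930), an outer mitochondrial membrane protein, was higher by 4.24 ± 0.62. AOX1D (AT1G32350), an alternative oxidase, had 2 reads over the wild-type libraries and 401 in med25-1, a ratio of 168 with a 95% counting interval of 46.3 to 1396. OM66 had a log2 fold change of 3.48 without med25-1 control replicate 2. AOX1D differed by at least 63.9-fold without wild-type control replicate 3. Heat shock genes counted 4 higher and 1 lower of 15, with 10 up and 1 down when adjusted over the list alone (camera adjusted p = 0.0073, adjusted p = 0.637 with an estimated correlation). Of 19 abscisic acid, cold and osmotic genes 4 were higher, CBF3 by 1.42 ± 0.26 (camera adjusted p = 0.0237, adjusted p = 0.547 with an estimated correlation). Flavonoid genes counted 2 lower of 5 (camera adjusted p = 0.00213, adjusted p = 0.414 with an estimated correlation). Photosynthesis genes counted 4 lower of 24 (camera adjusted p = 0.00515, adjusted p = 0.851 with an estimated correlation), with the Rubisco small subunit RBCS3B (AT5G38410) at -0.91 ± 0.19. Ribosome biogenesis genes counted none of 15 and were lower as a list (camera adjusted p = 0.00485, adjusted p = 0.748 with an estimated correlation). The heat shock call was lost without med25-1 control replicate 2, where its mean log2 fold change was 0.87 and not 1.70 (adjusted p = 0.0511, in a range of 5.3e-04 to 0.637 over its alternatives). The ribosome biogenesis call was lost without med25-1 control replicate 3, where its mean log2 fold change was -0.26 and not -0.43 (adjusted p = 0.0659, in a range of 1.2e-04 to 0.748 over its alternatives). The abscisic acid, cold and osmotic call was lost without wild-type control replicate 3 or med25-1 control replicate 3 (adjusted p of 0.0613 and 0.185 in that order, in a range of 0.00211 to 0.547 over its alternatives). Abscisic acid, cold and osmotic genes had a mean log2 fold change of 0.56, which was 0.31 without med25-1 control replicate 3. The heat shock score was 2.79 in med25-1 control replicate 2 and at most 1.37 in replicates 1 and 3. The ribosome biogenesis score was 4.37 in replicate 3 and 5.06 and 4.84 in replicates 1 and 2.

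Jasmonate genes went both ways under control conditions, with 1 of 27 higher and 2 lower. TAT3 (AT2G24850), a tyrosine aminotransferase, was higher by 7.14 ± 0.85, whereas CYP94B3 (AT3G48520), which inactivates jasmonoyl-isoleucine, stood at -5.00 ± 0.90 and the vegetative storage protein VSP2 (AT5G24770) at -2.35 ± 0.48. TAT3 had a log2 fold change of 8.56 without wild-type control replicate 3. CYP94B3 had a log2 fold change of -3.66 and -5.80 without wild-type control replicate 1 and med25-1 control replicate 3 in that order. Flowering genes counted 1 higher of 11, the FLC relative MAF4 (AT5G65070) at 4.41 ± 0.35 (camera adjusted p = 0.0404, adjusted p = 0.487 with an estimated correlation). MAF4 lies near MAF2 (AT5G65050), where reads outside exons made up 16.8% of reads in wild type and 8.86% in med25-1, with no overlap between the libraries of the lines, a measure chosen after values were seen. Of 54 core hypoxia genes 8 were higher and 4 lower (camera adjusted p = 0.519), AlaAT1 (AT1G17290), alanine aminotransferase, at 1.28 ± 0.23 and ETR2 at -1.17 ± 0.21. The 8 higher were 5, 3 and 2 without wild-type control replicates 1, 2 and 3, and 5 and 5 without med25-1 control replicates 2 and 3, the last with 2 lower. PCO1 was lower (-2.01 ± 0.48), a call lost without med25-1 control replicate 2 or 3 (adjusted p up to 0.0951 over the alternatives). PCO1 had a log2 fold change of -2.68 without med25-1 control replicate 1. Lists without a call held 4 higher genes of glycolysis and fermentation of 33, 1 lower gene of oxygen sensing of 16, and 2 higher and 2 lower circadian genes of 16, with PRR9 (AT2G46790) at 1.66 ± 0.24. They also held 2 lower ethylene genes of 16, 1 higher sugar starvation gene of 15, 2 higher iron genes of 11, and 2 higher and 2 lower light and shade genes of 16. The jasmonate and ethylene defence branch counted 1 lower of 3. Mediator, cell cycle and the root markers had no call. Median, mean and camera direction differed in sign for Mediator (-0.00, 0.01, higher, adjusted p = 0.927) and circadian (-0.10, 0.06, higher, adjusted p = 0.688). They also differed for sugar starvation (-0.01, 0.04, higher, adjusted p = 0.911). Adjusted over the list alone, the counts were 2 up and 0 down for glycolysis and fermentation genes, 4 up and 2 down for circadian genes and 0 up and 1 down for ethylene genes. They were 5 up and 0 down for abscisic acid, cold and osmotic genes and 3 up and 2 down for light and shade genes. The lists with no such count given kept theirs. PI was lower (-1.49 ± 0.42), a call lost without wild-type control replicate 1, 2 or 3 or med25-1 control replicate 1, 2 or 3 (adjusted p up to 0.114 over the alternatives). Single genes were nearly absent from one line: AT3G01345 (chromosome 3, 129138 to 130749), an uncharacterized protein-coding gene, stood at 122 ± 10.8 CPM in wild type and 0.0779 ± 0.0339 CPM in med25-1 (log2 fold change -10.48 ± 0.30, edgeR adjusted p = 2.7e-09). AT1G11280, an S-locus lectin protein kinase gene, had no wild-type read and was at least 243-fold higher in med25-1, and at least 139-fold without wild-type control replicate 3. The count of calls was 1990, 1554 and 1285 without wild-type control replicates 1, 2 and 3. It was 1861 and 1838 without med25-1 control replicates 2 and 3, and 5027 without med25-1 hypoxia replicate 3. It was 5177 in a fit of the control libraries alone, 6779 with voom and sample weights, and 1795 with a difference of at least 2-fold required. The share of higher calls was 49.5% in that fit of the control libraries, 48.2% with voom and 62.8% without med25-1 control replicate 3. The flowering call was lost without wild-type control replicate 1 or 3, med25-1 control replicate 1 or 3 or med25-1 hypoxia replicate 3 (adjusted p of 0.0548, 0.0574, 0.0554, 0.0724 and 0.0938 in that order, in a range of 0.010 to 0.487 over its alternatives). Jasmonate genes, not called as a list, were called higher without wild-type control replicate 1 or med25-1 control replicate 2 (adjusted p of 0.0168 and 0.00601 in that order), in a range of 0.00601 to 0.995 over its alternatives. Cell cycle genes, not called as a list, were called lower without wild-type control replicate 1 or med25-1 control replicate 2 (adjusted p of 0.00788 and 0.0403 in that order), in a range of 0.00788 to 0.873 over its alternatives.

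The fourth comparison set med25-1 against wild type under hypoxia. All 18 salicylate genes were again called higher, with a median log2 fold change of 4.84, which was 3.95 without med25-1 hypoxia replicate 3. PR2 stood at 4.87 ± 2.46 CPM (SD, n = 3) in wild type and 2099.9 ± 1850 CPM in med25-1 (log2 fold change 8.74 ± 0.88, SE; edgeR adjusted p = 9.3e-05). Its med25-1 mean was 1033 CPM without replicate 3. Of the 54 core hypoxia genes 13 were lower in the mutant and 2 higher. The lower ones were 7, 6 and 8 without wild-type hypoxia replicates 2 and 3 and med25-1 hypoxia replicate 3 in that order, and the higher ones 4 without med25-1 hypoxia replicate 2 or 3. PCO2, among the lower ones, stood at 18.9 ± 5.87 CPM against 48.7 ± 2.29 CPM (log2 fold change -1.36 ± 0.21, edgeR adjusted p = 0.00137). KIN1 (AT5G15960), a cold-inducible protein, stood at 2.40 ± 1.29 CPM against 51 ± 12.6 CPM (log2 fold change -4.31 ± 0.55, edgeR adjusted p = 3.9e-04). Of the 3 tested jasmonate and ethylene defence genes 2 were lower: ORA59 (AT1G06160), an activator of that branch, at -4.10 ± 0.65, and PDF1.2A, which had no read in med25-1, was at least 44.6-fold lower. PR2 had a log2 fold change of 7.72 without med25-1 hypoxia replicate 3. ORA59 had a log2 fold change of -5.00 without med25-1 hypoxia replicate 2. PDF1.2A differed by at least 28.8-fold and 24.1-fold without med25-1 hypoxia replicates 1 and 2 in that order.

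Under hypoxia 3933 genes were called between genotypes, 2181 higher (55.5%) and 1752 lower in med25-1. Limma on the quantile-normalized values turned this balance, with 2073 higher (46.7%) and 2370 lower. Of the edgeR calls, 1240 higher and 845 lower genes were also called under control conditions, against 196 and 142 for independent lists. The salicylate list (camera adjusted p = 7.9e-24, adjusted p = 0.156 with an estimated correlation, fry adjusted p = 0.00434) had a score of 1.80 ± 0.07 (SD, n = 3) in wild type and 7.09 ± 1.05 in med25-1, where replicate 3 was highest at 8.30. The core hypoxia list counted 4 up and 15 down when adjusted over the list alone (camera adjusted p = 0.0102, adjusted p = 0.547 with an estimated correlation). Called higher among all tested genes were ARD3 (AT2G26400) and AT4G17670, named after their values were seen. AT4G39675 stood at -1.34 ± 0.20 and ETR2 at -1.14 ± 0.18, whereas ADH1 (-0.32 ± 0.28, edgeR adjusted p = 0.444) and HB1 (0.57 ± 0.20, edgeR adjusted p = 0.0616) were not called. The core score was 4.83 in med25-1 hypoxia replicate 3 and 5.07 and 5.14 in replicates 1 and 2. PDC1 was lower (-1.47 ± 0.45), a call lost without wild-type control replicate 3, wild-type hypoxia replicate 2 or 3 or med25-1 hypoxia replicate 2 or 3 and with only the 2 groups compared fitted and with limma on quantile-normalized values (adjusted p up to 0.177 over the alternatives). HRE2 was lower (-1.23 ± 0.34), a call lost without wild-type hypoxia replicate 1 or 3 or med25-1 hypoxia replicate 3 (adjusted p up to 0.103 over the alternatives). Oxygen sensing counted 4 lower of 16 (camera adjusted p = 0.0424, adjusted p = 0.585 with an estimated correlation). The core hypoxia call was lost without wild-type hypoxia replicate 2, where its mean log2 fold change was -0.10 and not -0.19 (adjusted p = 0.0961, in a range of 5.9e-04 to 0.547 over its alternatives). The oxygen sensing call was lost without wild-type hypoxia replicate 2 or 3 or med25-1 hypoxia replicate 1 (adjusted p of 0.171, 0.0533 and 0.0881 in that order, in a range of 0.0069 to 0.585 over its alternatives). Glycolysis and fermentation counted 8 higher and 4 lower of 33, with a median of -0.05 and a mean of 0.10 (camera adjusted p = 0.528). PFK3 (AT4G26270), a phosphofructokinase, was higher by 1.85 ± 0.31 and GAPC1 (AT3G04120), glyceraldehyde phosphate dehydrogenase, by 1.06 ± 0.24.

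Heat shock genes counted 10 higher and 1 lower of 15 in med25-1 under hypoxia (camera adjusted p = 9.4e-05, adjusted p = 0.529 with an estimated correlation), with the chaperone HSP101 (AT1G74310) at 2.94 ± 0.52 and the coactivator MBF1C (AT3G24500) at 1.67 ± 0.29. Mitochondrial and oxidative stress genes counted 9 higher and 1 lower of 15 (camera adjusted p = 0.00213, adjusted p = 0.585 with an estimated correlation), OM66 at 5.80 ± 0.65 and the alternative dehydrogenase NDB2 (AT4G05020) at 3.29 ± 0.53. Flavonoid genes counted 4 lower of 5 (camera adjusted p = 0.00215, adjusted p = 0.397 with an estimated correlation), CHS at -2.29 ± 0.31. Sugar starvation genes counted 4 lower of 15, with 1 up and 10 down when adjusted over the list alone (camera adjusted p = 0.00964, adjusted p = 0.618 with an estimated correlation). MCCA (AT1G03090), of leucine breakdown, was lower (-0.92 ± 0.20), a call lost with only the 2 groups compared fitted (adjusted p up to 0.051 over the alternatives). Photosynthesis genes counted 2 lower of 24 (camera adjusted p = 6.9e-04, adjusted p = 0.753 with an estimated correlation). Their score was 11.66, 11.63 and 10.85 in med25-1 replicates 1 to 3, lowest in replicate 3, against 11.88 ± 0.05 (SD, n = 3) in wild type. The abscisic acid, cold and osmotic list counted 3 higher and 5 lower of 19 (camera adjusted p = 0.117), the lipid transfer protein LTP3 (AT5G59320) at -4.56 ± 0.80 and RD22 (AT5G25610) at -1.57 ± 0.33. Jasmonate genes counted 2 higher and 3 lower of 27 (camera adjusted p = 0.335), CYP94B3 at least 82.8-fold lower and VSP2 at -2.84 ± 0.48. The jasmonate and ethylene defence branch counted 2 lower of 3, 3 when adjusted over the list alone. Lists without a call held 3 higher flowering genes of 11, among them MAF5 (AT5G65080) at 2.37 ± 0.54, and 2 higher and 4 lower circadian genes of 16, with PRR9 at 1.98 ± 0.24 and PRR3 (AT5G60100) at -1.39 ± 0.22. They also held 4 higher and 2 lower ethylene genes of 16, with the synthesis gene ACS6 (AT4G11280) at 2.02 ± 0.45, 2 higher iron genes of 11, and 1 higher and 1 lower light gene of 16. HSP101, OM66, NDB2 and ACS6 had a log2 fold change of 2.18, 4.93, 2.37 and 1.39 without med25-1 hypoxia replicate 3. LTP3 had a log2 fold change of -5.55 without med25-1 hypoxia replicate 2. CYP94B3 differed by at least 53.4-fold and 44.7-fold without med25-1 hypoxia replicates 1 and 2 in that order. MAF5 had a log2 fold change of 3.01 without wild-type hypoxia replicate 2. Of Mediator only MED25 was called and of ribosome biogenesis and cell cycle none. Median, mean and camera direction differed in sign for ribosome biogenesis (-0.03, 0.02, lower, adjusted p = 0.99). Adjusted over the list alone, the counts were 9 up and 5 down for glycolysis and fermentation genes, 2 up and 5 down for circadian genes and 11 up and 1 down for heat shock genes. They were 11 up and 1 down for mitochondrial and oxidative stress genes, 0 up and 0 down for photosynthesis genes and 2 up and 1 down for iron genes. They were 0 up and 0 down for light and shade genes. The lists with no such count given kept theirs. Of the root markers 1 was higher and 1 lower, and PI was lower (-1.64 ± 0.32). The count of calls was 2606 and 2214 without wild-type hypoxia replicates 1 and 3, 2710 without med25-1 hypoxia replicate 3, and 2098 with a difference of at least 2-fold required. In a fit of the hypoxia libraries alone it was 1819, of which 1275 were higher, 70.1%. Photosynthesis genes had a mean log2 fold change of -0.45, which was -0.23 without med25-1 hypoxia replicate 3. Flowering genes, not called as a list, were called higher without wild-type control replicate 1 or 2, wild-type hypoxia replicate 1 or med25-1 hypoxia replicate 2 or 3 (adjusted p of 0.037, 0.0361, 0.0364, 0.0467 and 0.0296 in that order), in a range of 0.0143 to 0.529 over its alternatives. Abscisic acid, cold and osmotic genes, not called as a list, were called lower without med25-1 control replicate 3 (adjusted p = 0.025), in a range of 0.025 to 0.689 over its alternatives.

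Same-numbered wild-type and med25-1 hypoxia libraries correlated at 0.114 to 0.49, which does not establish that the numbers pair them. The number was also fitted as a block among the hypoxia libraries. With it 2843 genes were higher and 2847 lower in med25-1 under hypoxia. HB1 (log2 fold change 0.56, adjusted p = 0.0392) and BRX1-1 (AT3G15460), of ribosome biogenesis (0.56, adjusted p = 0.0365) were then called higher. PCO1 (-0.41, adjusted p = 0.0413) and HRA1 (-0.51, adjusted p = 0.0452) were called lower. Without the block these were at 0.57 ± 0.20, edgeR adjusted p = 0.0616, 0.56 ± 0.19, edgeR adjusted p = 0.0525, -0.41 ± 0.16, edgeR adjusted p = 0.0799 and -0.49 ± 0.28, edgeR adjusted p = 0.233. Oxygen sensing counted 1 higher and 6 lower with the block, but its list test no longer passed (adjusted p = 0.0592). Photosynthesis counted 8 lower, sugar starvation 10 lower, Mediator 3 higher and 3 lower, and ribosome biogenesis 1 higher. Iron counted 4 higher and 1 lower, and light and shade 2 higher and 2 lower.

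The last comparison asked whether the response to hypoxia itself differed between the genotypes. The core hypoxia score went from 2.04 ± 0.06 (SD, n = 3) to 5.23 ± 0.13 in wild type and from 2.22 ± 0.02 to 5.01 ± 0.16 in med25-1. The rise was 3.18 against 2.79 log2 units, a difference of -0.39 (two-sided exact permutation of genotype labels within each treatment, 400 arrangements, p = 0.01). Chance there means no genotype difference in either treatment, so this p does not test the rise alone. With hypoxia labels swapped only within the same-numbered pairs p was 0.0125, the smallest that these 160 arrangements can give. Taken by replicate number the difference was -0.17, -0.41 and -0.59 for numbers 1, 2 and 3, where the control libraries share only a number. The abscisic acid, cold and osmotic score rose from 3.43 ± 0.13 to 4.95 ± 0.09 in wild type and stood at 3.86 ± 0.33 and 4.30 ± 0.18 in med25-1. The mean log2 interaction of that list was -1.17, with CBF3 at -1.53 ± 0.35 (SE; edgeR adjusted p = 0.845).

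Single genes were not called: edgeR called 0 for the interaction, 910 had an unadjusted p under 0.05, and the smallest edgeR adjusted p was 0.155, for AT5G41900, an alpha/beta-hydrolase family gene. DESeq2 called 16 genes, 1 higher and 15 lower. Limma on the quantile-normalized values called 1, and voom with sample weights 0. The DESeq2 set held AT5G41900 (log2 interaction -2.58, DESeq2 adjusted p = 3.9e-05), the ethylene response factor ERF2 (AT5G47220; -2.06, DESeq2 adjusted p = 0.0101) and KIN1 (-3.21, DESeq2 adjusted p = 0.0456). AT5G41900 and ERF2 were named after their values were seen. PCO1 had an interaction of 1.60 ± 0.51, RBOHD of -1.30 ± 0.37, SUS1 of -1.65 ± 0.49 and ADH1 of -0.55 ± 0.44 (edgeR adjusted p of 0.929, 0.922, 0.929 and 0.947). On simulated data 14% of genes with a 2-fold interaction and 69% of those with a 4-fold one were recovered, so that smaller differences were mostly not detectable here.

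Of 19 lists, camera with a preset correlation called 6 for the interaction. The abscisic acid, cold and osmotic list was lower (adjusted p = 5.3e-14) and was the only one also called with an estimated correlation (adjusted p = 0.0235), with 0 up and 9 down of 19 when adjusted over the list alone. The core hypoxia list was lower (camera adjusted p = 4.8e-06, adjusted p = 0.29 with an estimated correlation), with 0 up and 1 down when adjusted over the list alone. Jasmonate genes (camera adjusted p = 1.9e-06, adjusted p = 0.547 with an estimated correlation) and sugar starvation genes (camera adjusted p = 4.6e-07, adjusted p = 0.297 with an estimated correlation) were lower as lists. Ribosome biogenesis genes were higher (camera adjusted p = 1.8e-06, adjusted p = 0.529 with an estimated correlation), as were heat shock genes (camera adjusted p = 0.0443, adjusted p = 0.759 with an estimated correlation). Median, mean and camera direction differed in sign for flowering (-0.07, 0.08, higher, adjusted p = 0.927) and light and shade (-0.08, 0.04, lower, adjusted p = 0.335). Adjusted over the list alone, the counts were 0 up and 1 down for jasmonate and ethylene defence genes. The lists with no such count given kept theirs. With the replicate block among the hypoxia libraries heat shock no longer passed (adjusted p = 0.0548). The salicylate list, with a median interaction of 0.10, was not called (camera adjusted p = 0.274). Jasmonate genes had a mean log2 interaction of -0.79, which was -0.32 without med25-1 control replicate 3. The heat shock call was lost without wild-type control replicate 1, med25-1 control replicate 1 or 3, wild-type hypoxia replicate 1, 2 or 3 or med25-1 hypoxia replicate 3 (adjusted p of 0.158, 0.423, 0.204, 0.218, 0.0555, 0.0664 and 0.516 in that order, in a range of 6.3e-06 to 0.759 over its alternatives). Heat shock genes had a mean log2 interaction of 0.25, which was -0.01, -0.05, 1.06, -0.06, 0.17, 0.42 and -0.21 without wild-type control replicate 1, med25-1 control replicates 1, 2 and 3, wild-type hypoxia replicate 1 and med25-1 hypoxia replicates 1 and 3 in that order. Ribosome biogenesis genes had a mean log2 interaction of 0.45, which was 0.27 without med25-1 control replicate 3. Glycolysis and fermentation genes, not called as a list, were called lower without wild-type hypoxia replicate 1 or med25-1 hypoxia replicate 3 (adjusted p of 0.024 and 0.0261 in that order), in a range of 0.024 to 0.943 over its alternatives. Salicylate genes, not called as a list, were called higher without med25-1 control replicate 2 or med25-1 hypoxia replicate 1 (adjusted p of 0.00183 and 0.0275 in that order), in a range of 0.00183 to 0.938 over its alternatives. Circadian genes, not called as a list, were called lower without wild-type control replicate 2, med25-1 control replicate 1, wild-type hypoxia replicate 1 or med25-1 hypoxia replicate 2 (adjusted p of 0.0422, 0.0262, 0.0289 and 0.0124 in that order), in a range of 0.0124 to 0.547 over its alternatives. Photosynthesis genes, not called as a list, were called lower without med25-1 hypoxia replicate 1 or 2 (adjusted p of 0.0114 and 0.0225 in that order) and higher without med25-1 hypoxia replicate 3 (adjusted p = 0.0246), in a range of 0.0114 to 0.938 over its alternatives. Cell cycle genes, not called as a list, were called higher without wild-type control replicate 1, med25-1 control replicate 2 or wild-type hypoxia replicate 1 (adjusted p of 0.00218, 0.0422 and 0.00121 in that order), in a range of 0.00121 to 0.861 over its alternatives. Light and shade genes, not called as a list, were called lower without med25-1 hypoxia replicate 1 (adjusted p = 0.0351), in a range of 0.0351 to 0.904 over its alternatives. The jasmonate score was 5.13 in med25-1 control replicate 3 and 4.25 and 3.89 in replicates 1 and 2, and the ribosome biogenesis score was 4.37 against 5.06 and 4.84.

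**Figure D3:**
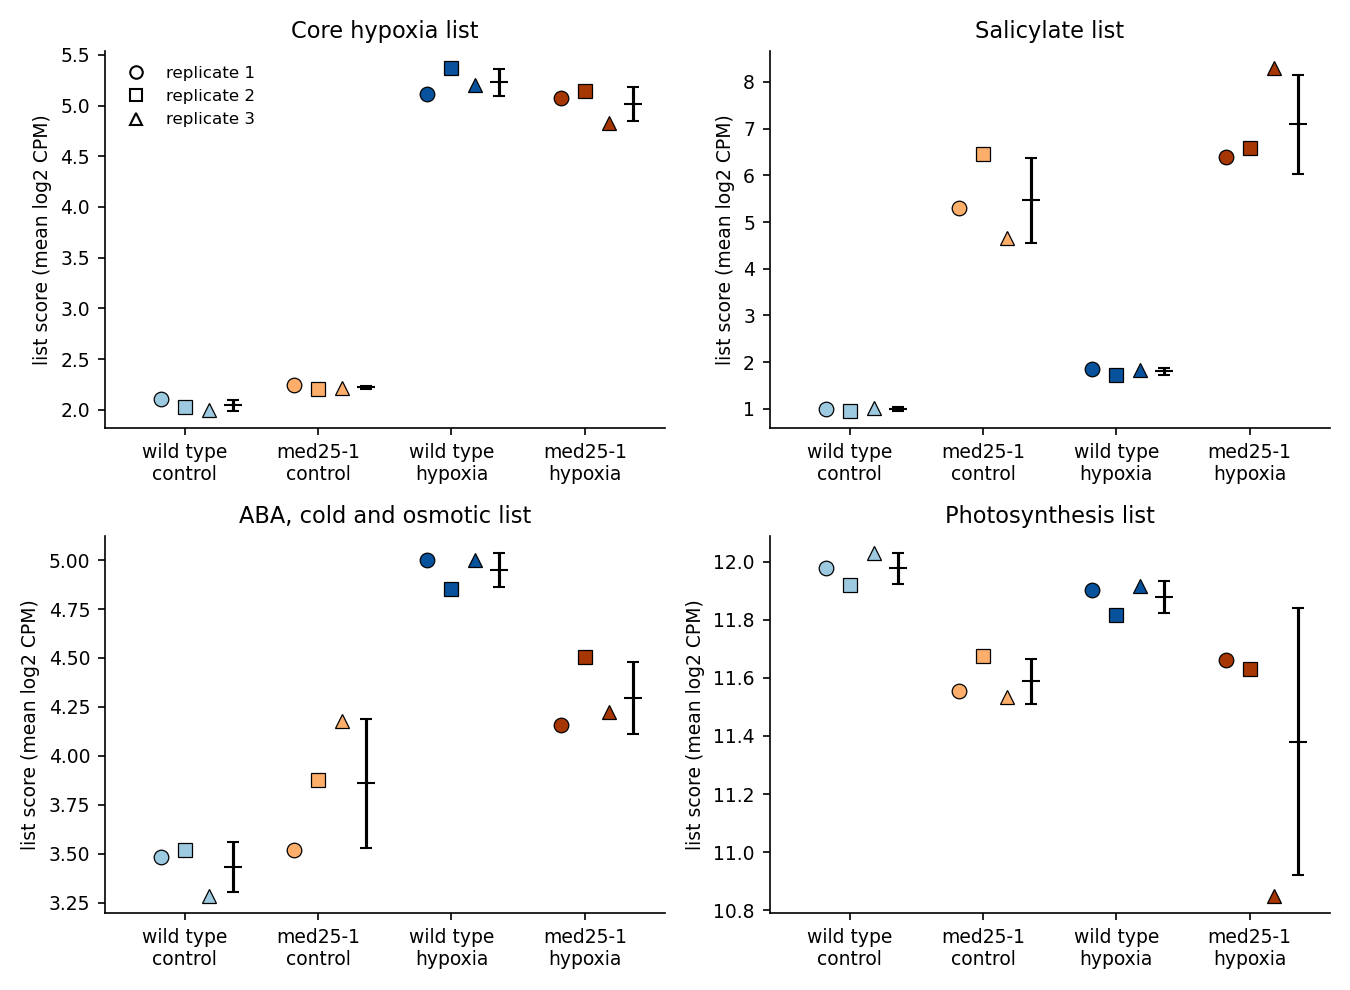
Score of 4 gene lists (mean log2 CPM over tested members, y axes not starting at 0) in each of the 12 libraries, by group, with black bars for the mean ± SD of 3 libraries. The mean salicylate score lies at 0.99 and 1.80 in wild type and at 5.47 and 7.09 in med25-1, and med25-1 hypoxia replicate 3 is the highest library for salicylate (8.30) and the lowest for photosynthesis (10.85).

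At a corrected p under 0.05 the authors' deposited table held 1840 of 33208 features higher and 2137 lower under hypoxia in wild type. In med25-1 it held 389 higher and 1181 lower. For med25-1 against wild type it held 2686 higher and 3884 lower under control conditions, and 995 higher and 2330 lower under hypoxia. Unlike in the main edgeR fit, lower ones prevailed there. The cause was not tested.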

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

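The tests of intron read shares, of their positions and of the starting level of the core list were chosen only after their results were seen. Reads outside the exons of MED25, which the main counts include, made up 8.78% of its reads in med25-1 control and 9.24% in med25-1 hypoxia. In this share each med25-1 library lay above every wild-type one. Of 11221 genes compared for intron share, 130 separated the med25-1 from the wild-type libraries, against 0.216% with random labels. They lay closer together on the chromosomes than shuffled genes (permutation over 62 bins of 2 Mb, p = 7.0e-04). Over 36 versions of the filters and bins the p ran from 5.0e-04, the smallest that 2000 permutations can give, to 0.0050. Against more unspliced RNA or DNA in all med25-1 libraries, the median gene's intron share differed by -0.0312 percentage points between genotypes, with overlapping libraries. Against uneven gene positions or annotation, the 55 genes that separated hypoxia from control showed no such spread (permutation p = 0.393), though they were fewer. A candidate explanation that stays open is that segments of the med25-1 line differ in sequence from wild type. How far calls of genes in such segments reflect it stays open too. This may concern AT4G17670, 1 of the 130, and MAF4 and MAF5 near MAF2, another of the 130. Genes called by genotype in both treatments, in the same direction and at least 2-fold, made up 112 of 1104 other tested genes in 4 bins, and 1101 of 16952 elsewhere (odds ratio 1.63, 95% interval 1.31 to 2.00, two-sided Fisher's exact p = 9.6e-06, with linked genes not independent). Those bins had at least 20 compared genes and a separating share over 3 times the mean. Among genes named as called by genotype they held MAF4, PRR3, ORA59, MAF5 and MCCA. Over 6 versions with lower shares required or thinner bins kept, 4 to 10 bins gave odds ratios of 1.40 to 1.63, with p of at most 1.4e-04. This excess does not decide between a difference in sequence and a difference in level.

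The core hypoxia list rose less in med25-1, with a difference between the genotypes' rises in its score of -0.391 log2 units, a difference below 0 in 41 of its 54 genes (permutation p = 0.01, and 0.0125 with hypoxia labels swapped only within same-numbered pairs) and a mean log2 interaction over its genes of -0.477. A single library as the whole cause is argued against by the value without med25-1 hypoxia replicate 3, -0.299 (SE 0.0902). Genes near the detection floor are argued against by the 28 core genes with at least 50 counts in every group, where it was -0.443 (SE 0.132). A higher starting level in med25-1 stays open, since the control libraries gave 45.4% of the difference and between 39.2% and 59.5% with single libraries left out. Under hypoxia alone the scores of the genotypes differed by -0.213 (two-sided exact permutation test, 20 arrangements, p = 0.2). That med25-1 plants respond less at these genes may be the biological side, as a hypothesis found and tested on the same libraries, and the list's test with an estimated correlation did not pass (adjusted p = 0.29).

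Other lists whose response to hypoxia differed between genotypes by camera's interaction test were the abscisic acid, cold and osmotic list, with a mean log2 interaction of -1.17, jasmonate genes at -0.792, sugar starvation genes at -0.454, ribosome biogenesis genes at 0.452 and heat shock genes at 0.255. With an estimated correlation the first of these passed (adjusted p = 0.0235), and the others had an adjusted p of 0.547, 0.297, 0.529 and 0.759 in that order. The jasmonate mean was -0.32 without med25-1 control replicate 3. The ribosome biogenesis mean was 0.27 without med25-1 control replicate 3. The heat shock call was lost without wild-type control replicate 1, med25-1 control replicate 1 or 3, wild-type hypoxia replicate 1, 2 or 3 or med25-1 hypoxia replicate 3 (adjusted p up to 0.516, in a range of 6.3e-06 to 0.759 over its alternatives). Heat shock genes had a mean log2 interaction of 0.25, which ran from -0.21 to 1.06 with single libraries left out.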

How the results depend on the processing

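Unique exon reads, voom and the other settings so marked above were chosen only after results were seen. Counts of called genes in the order hypoxia in wild type, hypoxia in med25-1, genotype under control and genotype under hypoxia were 1181, 961, 3115 and 3933. In fits of only the groups compared they were 2408, 175, 5177 and 1819. Chi-square per degree of freedom between replicates was 4.17 to 14.4 in wild-type control and 30.3 to 81.9 in med25-1 hypoxia. A shared spread may be too wide for the former and too narrow for the latter. With at least a 2-fold change required they were 650, 513, 1795 and 2098, fewer by construction. With voom hypoxia in wild type and genotype under control gave 5469 and 6779, and with DESeq2 hypoxia in med25-1 gave 1926. For the interaction DESeq2 called 16 and limma on the quantile-normalized signal 1, against 0. Leaving out single replicates moved the counts between 559 and 1933, 323 and 1841, 1285 and 5027, and 2214 and 5124. The 1933 and 5027 came without med25-1 hypoxia replicate 3, in neither comparison. The causes were not tested. Other settings stayed within 1.5 times. The counts of called members moved by over 1.5 times without at least 1 library in 69 of 88 pairs of a list and a comparison, many with few called members. The core score difference lay between -0.454 and -0.299, with p of 0.01 to 0.025, over the alternatives. MED25 under hypoxia in med25-1 lay between -0.75 and -0.37 on the log2 scale with single replicates left out. Of the 95 set tests 39 passed, 5 with an estimated correlation and 23 with fry, which ask stricter or other questions. The photosynthesis interaction turned from lower to higher without med25-1 hypoxia replicate 3 (adjusted p = 0.0246), the library lowest in that list, with adjusted p of 0.0114 to 0.704 over all single replicates left out. Of called named genes 37 of 48, 25 of 46, 37 of 55 and 47 of 65 kept their call in every setting run, and none changed direction.

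Over all groups, deviations from group means correlated between same-numbered libraries from -0.313 to 0.49 (18 pairs) and between others from -0.445 to 0.301, and 4 of 12 libraries correlated best with their own number. These values do not establish pairing by number in any groups, and among the hypoxia libraries it was fitted only as a possibility. With the replicate block in all groups the counts were 1136, 800, 3079 and 3810, and 0 for the interaction. With the replicate block among hypoxia libraries they were 5690 for genotype under hypoxia and 0 for the interaction. That block ended the list calls of oxygen sensing under hypoxia and of heat shock for the interaction, and added calls of HB1, BRX1-1, PCO1 and HRA1 under hypoxia. It changed no other call of a named gene or list. Each pairwise count was also taken over all 10 splits of its 6 libraries, where 1 split, the real one, gave as many genes (1181, 961, 3115 and 3933) and the highest other gave 0 in each, and 10 splits are too few for a share under 0.05. Under hypoxia 4 of the 10 splits part every pair of the same number, the real one among them, and the others keep same-numbered pairs together. For the interaction the real count was 0, so that all 60 of 60 splits gave as many by construction, with 17 as the highest other, and the comparison says nothing there. Depth limited med25-1 hypoxia replicate 3 most, at 7170796 reads.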

Other observations

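The genes CYP86A2, GDH2 and CESA5 and the tests for wild-type plants in a library were chosen only after results were seen. Genes outside the lists also responded to hypoxia differently by genotype with DESeq2, though none passed with edgeR. CYP86A2 (AT4G00360), a fatty acid hydroxylase of cutin synthesis, had a log2 interaction of -1.87 (DESeq2 adjusted p = 0.00636, edgeR adjusted p = 0.845) and GDH2 (AT5G07440), glutamate dehydrogenase, of -1.42 (DESeq2 adjusted p = 0.0432, edgeR adjusted p = 0.845). CESA5 (AT5G09870), a cellulose synthase subunit, was the one gene above 0, at 0.65 (DESeq2 adjusted p = 0.0432, edgeR adjusted p = 0.845).

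The med25-1 hypoxia replicate 3 library stood apart from replicates 1 and 2, with a salicylate score higher by 1.82 log2 units, and lower depth as the cause is argued against by a gap of 1.81 after the other libraries were thinned to 7170796 reads. A library wholly of wild-type plants is argued against by its MED25 intron share of 7.36%, above every wild-type library. Wild-type plants in part of it would move its scores toward wild type, but its salicylate score was 8.30, against 6.39 and 6.58 in replicates 1 and 2 and a mean of 1.80 in wild-type hypoxia, and its photosynthesis score 10.85, against 11.66, 11.63 and 11.88. Across genes, which are not independent replicates, its deviation from replicates 1 and 2 correlated with the genotype difference under control conditions, which shares no library with it (Pearson's r 0.55, Spearman's rho 0.58). A candidate explanation is that these plants were further along the difference that sets med25-1 apart from wild type, as a hypothesis, with differences in handling or harvest not tested.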
